A study of Mus musculus with 80 samples.

How the data were processed

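Gene expression was measured in cross sections of mouse tibialis anterior muscle with the NanoString GeoMx mouse whole transcriptome atlas, in which barcoded probes are released by light from a chosen area of a tissue section and counted. The labels describe 8 micron sections of flash-frozen muscle from C57Bl/6 mice that expressed P301L tau or were controls. The name of the deposited data includes P301L-AAV8, where AAV8 is a viral vector. Effects of the way tau was delivered were not tested apart from those of tau. Each of the 80 regions was one of 4 types named in the labels: normal fibres, fibres with central nuclei, nerve bundle, or surrounding artery. How the regions were chosen and outlined is not given in the sources used here. Treatment, animal, labelled sex and region type were taken from the labels, and the slide of each region from the header of the deposited table.

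The values are in the unit signal: per the file headers, the authors deposited upper-quartile (Q3, the third quartile) normalised probe counts on a linear scale, with no log and no background subtraction. The third quartile over the 10842 deposited genes was 79.1 in 78 of the 80 regions. The aligner, the counting software and the rule by which genes entered the table are not given in the sources used here, beyond the mm10 genome build in the submitters' processing notes. The low values of a region are whole multiples of one step (tolerance 0.02 of a step), and this step was used only to give each region's total count and Q3 count. The recovered counts were not used in any test. The depth bears on precision through counting error, and so does the negative probe value, the signal of probes that match no gene, which is the background of the assay. No region lists a gene at 0, and the lowest value was 2.26 against negative probe values of 17.2 to 53.2.

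A gene was tested when its value was at least 1.5 times the region's negative probe value in at least 10% of the regions. This kept 10188 genes and left out 654. Values were transformed as log2 of the value plus 1 and averaged over the regions of one type in one animal, so that the animal was the unit of replication. Tau was compared with control in each region type and, as the main comparison, over the mean of normal fibres, nerve bundle and surrounding artery, with labelled sex as a covariate. Tau was also compared with control within each labelled sex, and labelled males with labelled females among controls. The other region types were compared with normal fibres as differences within an animal (12 animals, 11 for central nuclei), and the difference between tau and control animals in those differences was tested as an interaction. The pairing rests on the animal named in the labels. Models were fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend, Benjamini-Hochberg adjustment over the genes tested, threshold 0.05), and tables were read with the data.table package (version 1.17.8). Errors on log2 differences are standard errors (SE) of the fitted value. Differences given by slide and means per group are not adjusted for any covariate. A difference fitted with labelled sex as a covariate can therefore depart from them. Means per group are of log2 values, with the SD between animals.

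Gene lists for 37 pathways, cell types and gene families were written from general knowledge of muscle, nerve and tau biology, and 31 had at least 5 members tested. Each of these was compared with all other tested genes by camera (limma) with a preset correlation of 0.01 between members, and again with the correlation estimated from the data. Camera is relative: a list can be ranked down while its median is above 0 when other genes are higher still. Members were also adjusted over the list alone. The genes named are, for a comparison with no call, taken from the 5 with the smallest p, named as not passing. To these come up to 4 members with the smallest p from each list called by camera or holding members past the threshold, and fixed markers: Mapt, the Y-linked Ddx3y, Uty and Eif2s3y, and Acta2, Myh11, Pecam1, Myh3, Myh8, Pax7, Chrna1 and Myog. Ncam1 was below the filter and Xist, Kdm5d and Mbp were not analysed here. Positions are from a RefSeq annotation of mm10, in which 10164 of the tested symbols were found.

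The comparisons, the filter, the lists, the rule for named genes and a first set of alternative settings were fixed before the data were examined. These settings changed the pseudocount to 5, dropped the filter or tightened it to 2 times the negative probe in 50% of regions, applied quantile normalisation, subtracted the negative probe value, left out each animal or the region whose name carries the word FLAG, took 1 region per animal and type, dropped the sex covariate, added slide as a covariate, ignored the pairing, and used an animal random effect. Alternatives chosen after seeing the data added the negative probe value as a covariate, alone or with slide, left out the animals of slide 2, left out the 13 regions whose Q3 was 30 counts or fewer, weighted animals by limma's array weights, combined slide with subtraction of the negative probe, and added slide to the comparison of labelled sexes in controls. The default method for array weights stopped before it converged in some fits, so the gene by gene method was used. The fits were tested on simulated data with 50 changed genes per size and no slide structure: the main comparison recovered 78% of genes changed by 1 log2 unit and 26% of those changed by 0.5, and the artery comparison recovered 94% of those changed by 0.5. No 2 regions were duplicates, since the most alike pair of columns shared 7.70% of their values.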

Results

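Spatial expression profiles were collected from the tibialis anterior, a mainly fast-twitch muscle of the lower leg, of 6 mice expressing P301L tau and 6 control mice. P301L is a mutation of the microtubule-binding protein tau known from inherited frontotemporal dementia. Control animals gave 41 regions and tau animals 39. There were 22 regions of fibres with central nuclei (11 control, 11 tau), 18 of nerve bundle (9 and 9), 20 of normal fibres (11 and 9) and 20 surrounding an artery (10 and 10). Tau animal T30 had no region with central nuclei. The labels give 3 female and 3 male control mice and 4 female and 2 male tau mice, whereas the design text of the series states 3 per sex and treatment.

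The regions lay on 3 slides, each with 2 control and 2 tau animals, and the slides differed in depth and background. Total counts ran from 312262 to 1288880 on slide 1, from 315108 to 3356100 on slide 2 and from 145488 to 2168380 on slide 3, with medians of 552840, 2248740 and 1292900. The negative probe value was 25.8 ± 5.24 on slide 1 (SD, n = 27 regions), 46.1 ± 2.99 on slide 2 (n = 25) and 34.8 ± 5.16 on slide 3 (n = 28). Slide explained 88.1% of the first principal component, which held 77.2% of the variance, and treatment explained 3.61%. On the second component, with 6.76% of the variance, slide explained 7.72%, treatment 33.8% and labelled sex 26.9%. Depth and background also differed between treatments within slides. The log2 total count was higher in tau animals by 0.88 (two-sided exact permutation p = 0.00926 over 216 assignments within slides), and by 0.95, 0.43 and 1.26 on slides 1, 2 and 3. The log2 negative probe value was higher by 0.23 (exact permutation p = 0.0463), and by 0.25, 0.09 and 0.34 on the 3 slides.

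**Figure D1:**
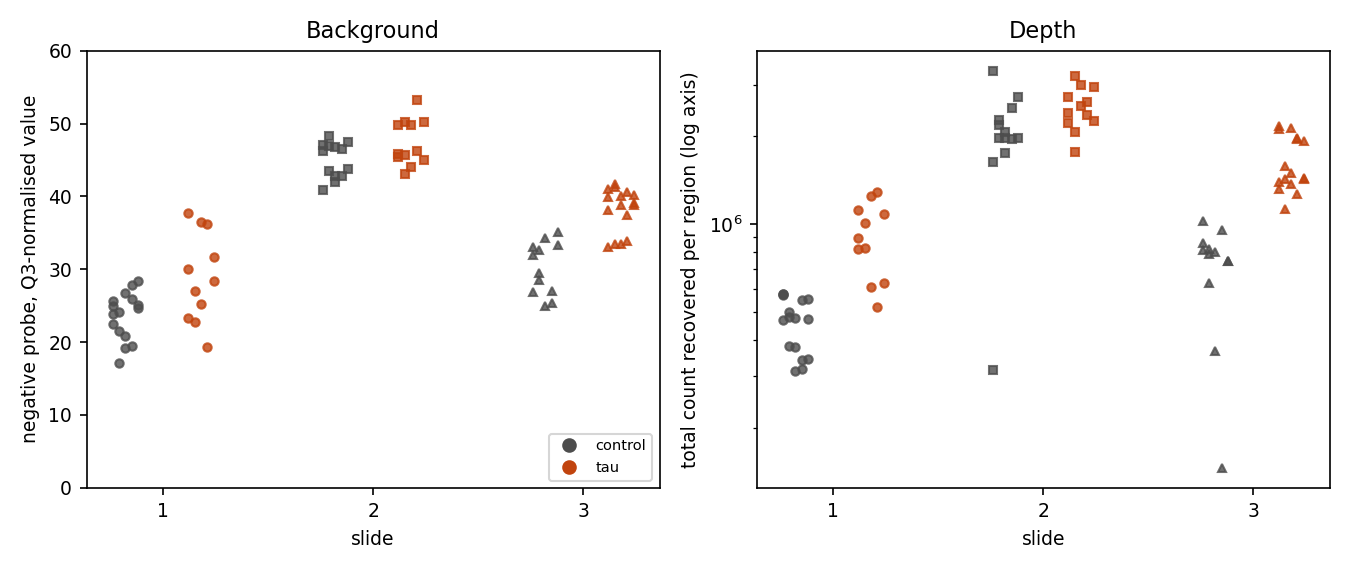
Negative probe value (signal, the background of the assay) and total count (log axis) of each region by slide, for control and tau animals. Slide 2 had the highest background, 46.1 on average, and within each slide the tau animals had the higher mean background and total count.

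Genes on the Y chromosome, which female mice lack, were higher in the labelled female controls than in the labelled male controls. Eif2s3y, a translation factor subunit gene, had a log2 value of 5.99 ± 0.62 in labelled females and 4.01 ± 0.50 in labelled males (SD, n = 3 each), a difference of -1.98. Ddx3y, an RNA helicase gene, differed by -1.34 (6.10 ± 0.19 and 4.76 ± 0.50) and Uty, a histone demethylase gene, by -0.49. Within slides 1, 2 and 3, each with 1 labelled male and 1 labelled female control, Eif2s3y differed by -3.10, -0.99 and -1.86 and Ddx3y by -1.95, -0.62 and -1.46. Uty differed by -0.85, -0.49 and -0.11, the last within its SD of 0.30 between regions. Among tau animals Eif2s3y was 6.15 in labelled female T13 and 3.91 to 4.58 in labelled females T30, T20 and T7, and 5.20 and 5.88 in labelled males T14 and T15. The exact permutation p of each control difference was 0.1, the smallest that 3 against 3 animals allow. Sex is therefore named as labelled throughout.

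**Figure D2:**
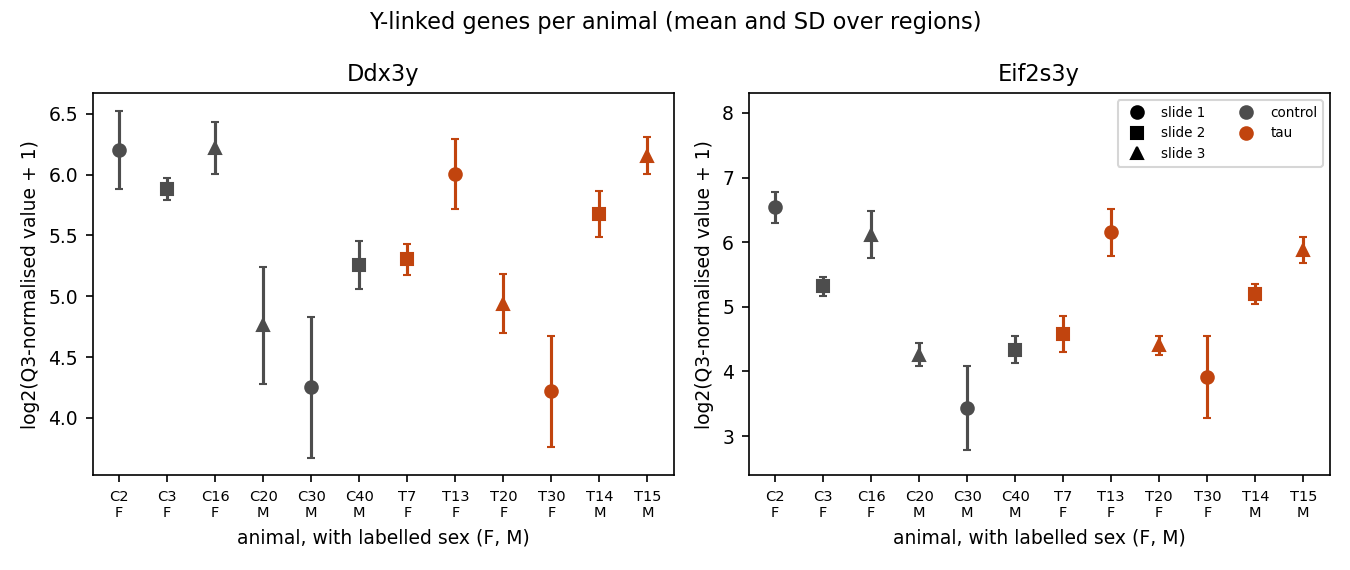
Log2 value of Ddx3y and Eif2s3y in each animal (mean and SD over its regions), by treatment and labelled sex. The 3 labelled female controls lie above the 3 labelled male controls for both genes.

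The first question was whether P301L tau altered muscle expression over normal fibres, nerve bundle and surrounding artery together. Mapt, the mouse tau gene (chromosome 11, 104229409 to 104332090, mm10), differed by 0.03 ± 0.12 (SE, n = 6 and 6), with -0.08, -0.07 and 0.28 on slides 1, 2 and 3. Whether its probe reads the human transgene is not given in the sources used here. The smallest p belonged to Taf13, a subunit of the general transcription factor TFIID (chromosome 3, 108571699 to 108582068). It stood at 6.03 ± 0.11 in tau and 5.57 ± 0.12 in control animals (SD). Its log2 difference of 0.46 ± 0.0996 (SE) was positive on each slide (0.50, 0.28 and 0.62). Also among the smallest were Gramd1b (0.39 ± 0.0932) and the guanylate kinase gene Guk1 (0.44 ± 0.118). Utrn, whose product utrophin is enriched at the neuromuscular junction, was another, at 0.37 ± 0.0952 (0.53, 0.14 and 0.49 by slide). Of 10188 genes limma called 0, with a lowest adjusted p of 0.873, and 202 had an unadjusted p under 0.05. A nominal 5% of the genes is 509.4, and other random splits of the animals gave a median of 71. This fit leaves out slide, so differences between slides enter its error. Its covariate is the labelled sex, which the Y-linked values contradict in the controls. Limma again called 0 with slide as a covariate (2099 at an unadjusted p under 0.05). The lowest adjusted p was then 0.0636, and ran from 0.0455 to 0.9999 over all alternatives. The 95% interval of a typical gene reached 0.37 to either side.

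Gene lists were ranked in both directions in this comparison. Of the acetylcholine receptor and neuromuscular junction genes, 16 of 16 were higher in tau (median log2 difference 0.26). They include Utrn, the transcription factor gene Etv5 (0.40 ± 0.138) and the receptor subunits Chrnb1 (0.27 ± 0.0959) and Chrne (0.36 ± 0.139). The camera adjusted p was 5.5e-06, and adjusted p = 0.287 with estimated correlation. No member passed over all genes and 1, Utrn, passed when adjusted over the list alone. Of the denervation response genes 11 of 12 were higher (median 0.23, camera adjusted p = 0.00416, adjusted p = 0.646 with estimated correlation), with 1 past the threshold adjusted over the list alone. They included the cell cycle inhibitor gene Cdkn1a (0.47 ± 0.126), Ankrd1 (0.73 ± 0.274) and the receptor subunit gene Chrna1 (0.48 ± 0.188). The 6 Schwann cell markers were all higher (median 0.33, camera adjusted p = 0.0104, adjusted p = 0.729 with estimated correlation, 0 members adjusted over the list alone), with the myelin gene Prx at 0.41 ± 0.225. With slide as a covariate the medians of these 3 lists were 0.25, 0.21 and 0.31.

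Genes of energy metabolism and of fast fibre contraction ranked lower in tau. Oxidative phosphorylation had a median of -0.16 with 8 of 36 above 0 (camera adjusted p = 8.5e-06). Fatty acid use had -0.21 with 3 of 19 above 0 (camera adjusted p = 9.9e-05). It includes Pdk4, an inhibitor of pyruvate use, at -0.72 ± 0.435 and the carnitine palmitoyltransferase gene Cpt2 at -0.40 ± 0.264. Fast fibre contractile genes had a median of -0.19 and glycolysis genes -0.14 (camera adjusted p = 0.0104 for each). Heat shock and chaperone genes had -0.05 (0.0457) and autophagy and lysosome genes -0.02 (0.0471). With an estimated correlation the adjusted p was 0.729 for each of these 6 lists. The heat shock call ended with slide as a covariate (camera adjusted p = 0.0611, and 1.3e-05 to 0.936 over all alternatives). It was lost in 15 of 27 alternatives, and the direction changed without a call in 4 more. The autophagy call was lost in 13 of 27, and the direction changed without a call in 2 more and with one in 1. The smooth muscle call below was lost in 11 of 26. Immediate early genes had a median of -0.11 (camera adjusted p = 0.00167, adjusted p = 0.350 with estimated correlation, Dusp1 -0.53 ± 0.308). Circadian clock genes had -0.15 (camera adjusted p = 0.00107, adjusted p = 0.440 with estimated correlation, Per1 -0.46 ± 0.211). Smooth muscle markers had a median of -0.03 (camera adjusted p = 0.0174, adjusted p = 0.498 with estimated correlation), with Acta2, smooth muscle actin, at -0.71 ± 0.266. In these 9 lists 0 members passed, over all genes or adjusted over the list alone. The lists ranked higher lie near the background and several ranked lower stand far above it. The median member stood 0.54 log2 units over the negative probe for the junction list and 0.36 for denervation. It stood 3.34 over it for oxidative phosphorylation and 7.22 for fast fibre genes. Over all genes the median difference was 0.10, and over the 500 genes with the highest values it was -0.19. With the negative probe value as a covariate the ranks of oxidative phosphorylation, fast fibre and glycolysis genes turned to higher in tau. Without regions of 30 counts or fewer these lists and autophagy and lysosome genes ranked higher in tau, with camera calls.

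The other 19 lists tested passed no threshold. Slide as a covariate gave camera calls for 2 of them, tau and its kinases lower (adjusted p = 0.0350, and 0.00566 to 0.729 over all alternatives) and neutrophil and mast cell markers higher (adjusted p = 0.0476, and 0.0228 to 0.833). Both had an adjusted p of 0.631 with estimated correlation. Medians were -0.02 for tau and its kinases, -0.01 for microtubule genes, 0.01 for muscle atrophy, 0.13 for satellite cell and regeneration, 0.13 for slow fibre contractile genes, 0.03 for the unfolded protein response and 0.01 for the proteasome. They were 0.11 for the interferon response, 0.09 for antigen presentation, 0.07 for complement and inflammation, 0.05 for extracellular matrix and 0.01 for oxidative stress. Among cell type markers they were 0.05 for endothelial cells, 0.03 for pericytes, 0.04 for fibro-adipogenic progenitors, 0.07 for macrophages, 0.32 for neutrophils and mast cells, 0.11 for adipocytes and 0.15 for tendon. The camera test ranks against other genes, so satellite cell genes, for example, ranked down although their median was above 0. With too few members for a test, medians were 0.33 for the perineurial marker, 0.28 for the T cell marker, 0.17 for B and plasma cells, 0.06 for red blood cells, 0.15 for motor axon transcripts and -0.11 for Y-linked genes. The fixed regeneration markers had intervals that included 0: Myh3 0.17 ± 0.161, Myh8 0.21 ± 0.229, Pax7 0.26 ± 0.194 and Myog 0.02 ± 0.125. So did Myh11 (0.05 ± 0.17) and the endothelial Pecam1 (0.31 ± 0.228).

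In normal fibres of tau animals, fast fibre contractile genes ranked lower (median -0.42, 4 of 19 above 0, camera adjusted p = 0.00371, adjusted p = 0.941 with estimated correlation). Slow fibre genes ranked higher (median 0.29, 12 of 13 above 0, camera adjusted p = 0.0466, adjusted p = 0.941 with estimated correlation), a call that ended with slide as a covariate (camera adjusted p = 0.0937, median 0.25, and adjusted p from 0.00368 to 0.976 over all alternatives). The slow myosin light chain gene Myl2 differed by 0.73 ± 0.26, the calcium store gene Casq2 by 0.59 ± 0.285 and the slow myosin gene Myh7 by 0.48 ± 0.267 (SE, n = 6 and 6). Circadian clock genes (median -0.19, camera adjusted p = 0.00371), glycolysis (-0.08; 0.0186) and tau and its kinases (-0.06; 0.0466) also ranked lower, and each had an adjusted p of 0.941 with estimated correlation. Over the alternatives the call was lost in 16 of 27 for tau and its kinases, in 14 for glycolysis, which changed direction in 2 more, in 12 for fast fibre genes and in 15 of 26 for slow fibre genes. Slow fibre genes changed direction without a call in 1 more. In these 5 lists 0 members passed when adjusted over the list alone. Guk1 (0.57 ± 0.152), Atp9a (0.52 ± 0.153), Utrn (0.47 ± 0.142), 9030624G23Rik (0.46) and the lysyl oxidase gene Loxl1 (0.58 ± 0.183) had the smallest p. Limma called 0 genes (lowest adjusted p 0.984, 166 at an unadjusted p under 0.05).

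With slide as a covariate limma called 51 genes in normal fibres, 46 lower and 5 higher in tau. The count at an unadjusted p under 0.05 was 1535. The genes named here were chosen after their values were seen. Lower genes included Mylk4, a muscle myosin light chain kinase gene, at -1.19 ± 0.18 (SE, limma adjusted p 0.00867). It was lower on each of slides 1, 2 and 3 (-0.67, -0.92 and -1.66). The LIM domain gene Fhl3 stood at -0.67 ± 0.104 (-0.53, -0.66 and -0.57 by slide). Also lower were Asb2 (-0.79 ± 0.119), Sorbs2 (-0.85 ± 0.136), the AMP deaminase gene Ampd1 (-0.77), the sarcoplasmic calcium release channel gene Ryr1 (-0.65), the phosphorylase kinase gene Phka1 (-0.64) and the chaperone gene Vcp (-0.55). The higher genes were Slc12a8 (0.47), Slc26a3 (0.51), Plscr5 (0.53), Sft2d3 (0.46) and Tmem19 (0.67). Over all alternatives of this comparison the lowest adjusted p ran from 0.00867 to 0.99997. The count changed widely with the animal left out. It was 9 without control C16, 3 without C2, 23 without C3, 23 without C20, 8 without C30 and 33 without C40. It was 10 without tau T13, 9 without T20, 14 without T30, 95 without T7, 44 without T14 and 14 without T15. With slide and the negative probe value as covariates it was 0 (746 at an unadjusted p under 0.05 in limma).

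**Figure D3:**
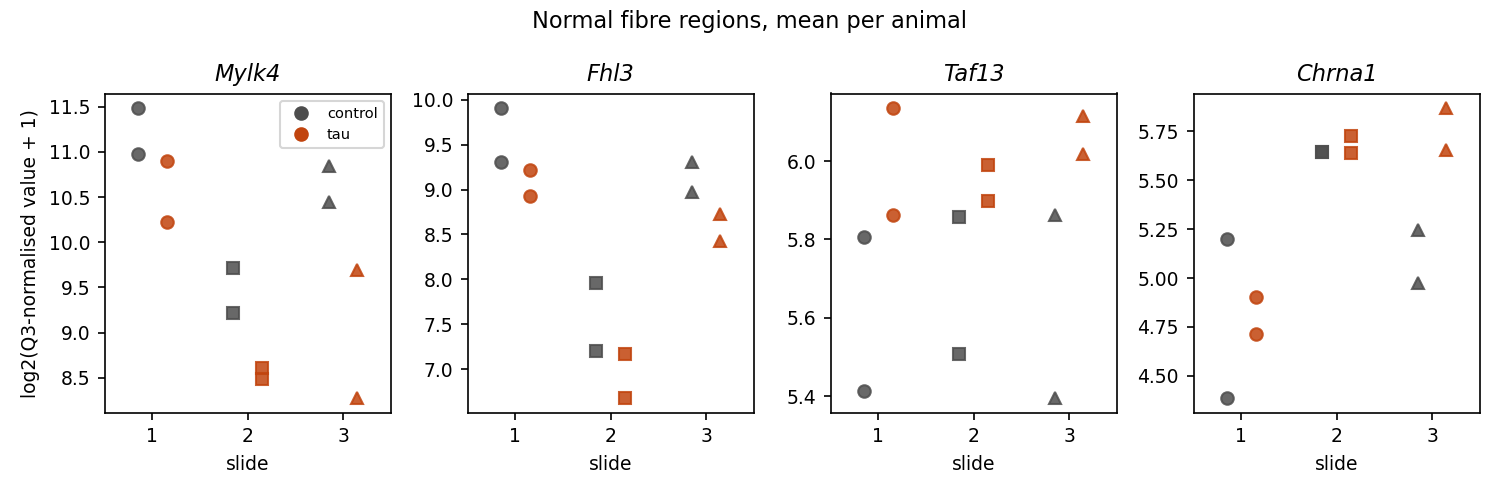
Log2 value of Mylk4, Fhl3, Taf13 and Chrna1 in normal fibres of each animal, by slide and treatment. Mylk4 and Fhl3 differ between tau and control by -0.67 and -0.53 on slide 1, -0.92 and -0.66 on slide 2, and -1.66 and -0.57 on slide 3.

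In fibres with central nuclei, a mark of regenerated muscle fibres, oxidative phosphorylation genes ranked lower in tau (median -0.35, 6 of 36 above 0, camera adjusted p = 3.1e-05, adjusted p = 0.777 with estimated correlation). Heat shock genes (-0.24, camera adjusted p = 0.00173), fast fibre genes (-0.31), glycolysis (-0.26), fatty acid use (-0.17), circadian clock genes (-0.14) and immediate early genes (-0.06) were ranked lower too, as were 3 other lists. The clock gene Per1 stood at -0.59 ± 0.18 and Dusp1 at -0.76 ± 0.303. The lowest adjusted p of any list with estimated correlation was 0.728. The histone gene H2bu2 had the smallest p, at 6.54 ± 0.22 in tau and 5.78 ± 0.23 in control animals (SD, n = 5 and 6), a difference of 0.76 ± 0.164 (SE). Next came the homeobox gene Prrx2 (0.71 ± 0.176), Smim22 (0.75 ± 0.201), the Wnt inhibitor gene Sost (0.48 ± 0.135) and Msc, the repressor of myogenic factors musculin (0.57 ± 0.162). The developmental myosin genes Myh3 (0.32 ± 0.213) and Myh8 (0.08 ± 0.164) did not pass, nor did Myog (0.13 ± 0.207). Here limma called 0 genes (lowest adjusted p 0.686, 376 at an unadjusted p under 0.05). Adding slide as a covariate gave 1 call (1907 at an unadjusted p under 0.05), Mylk4 (-1.05), named after its value was seen. With the negative probe value as a covariate, oxidative phosphorylation, fast fibre, glycolysis, fatty acid and proteasome genes ranked higher in tau, not lower. Calls were lost in 15 of 27 alternatives for tau and its kinases, 13 for muscle atrophy and 11 for the proteasome, the 3 other lists. The direction changed without a call in 1 more for tau and its kinases, 1 for muscle atrophy and 3 for the proteasome. The 500 genes with the highest values had a median of -0.34 against 0.10 for all genes.

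In nerve bundle regions the tau animals had lower values of Acta2, smooth muscle actin (chromosome 19, 34240336 to 34255585), at 5.77 ± 0.30 against 6.95 ± 0.83 in controls (SD, n = 6 and 6). The difference fitted with labelled sex as a covariate was -1.25 ± 0.312 (SE). By slide and without that covariate it was -1.16, -0.55 and -1.84 on slides 1, 2 and 3. The fitted difference did not pass. Junction genes ranked higher (median 0.40, 15 of 16 above 0, camera adjusted p = 0.000114, adjusted p = 0.144 with estimated correlation). They include the acetylcholinesterase gene Ache (0.90 ± 0.363), Chrna1 (0.67 ± 0.232, by slide 0.81, 0.16 and 1.31), the receptor kinase gene Musk (0.52 ± 0.19) and Chrnb1 (0.43 ± 0.141). Denervation genes (median 0.44, 11 of 12 above 0, camera adjusted p = 0.000343, adjusted p = 0.169 with estimated correlation) ranked higher as well. So did Schwann cell markers (median 0.46, 6 of 6, camera adjusted p = 0.00421, adjusted p = 0.449 with estimated correlation), with S100b at 0.47 ± 0.239. Fatty acid use (median -0.60, 2 of 19 above 0, camera adjusted p = 1.0e-13, adjusted p = 0.215 with estimated correlation) ranked lower, with Pdk4 at -1.04 ± 0.423. Oxidative phosphorylation ranked lower too (median -0.40, 1 of 36, camera adjusted p = 8.4e-15, adjusted p = 0.455 with estimated correlation). So did smooth muscle markers (median -0.23, camera adjusted p = 1.7e-05, adjusted p = 0.144 with estimated correlation) and 6 further lists. Of the smooth muscle markers 1, Acta2, passed adjusted over the list alone, as did 0 members of the other lists of this comparison.

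Other genes with the smallest p in nerve bundle were Cyp2d12 (0.80 ± 0.22), the dystroglycan gene Dag1 (0.63 ± 0.173), the ubiquitin conjugating enzyme gene Ube2r2 (0.57 ± 0.168) and Tstd2 (0.64 ± 0.188). Limma called 0 genes (lowest adjusted p 0.837, 243 at an unadjusted p under 0.05), and 0 with slide as a covariate (1033). With the negative probe value as a covariate the glycolysis list turned from lower to higher in tau. Oxidative phosphorylation, circadian clock and oxidative stress genes each changed direction without a call in 2 of 27 alternatives. The call was lost in 15 more for oxidative stress, in 14 for circadian clock genes and in 11 each for glycolysis, heat shock genes and pericyte markers. Glycolysis changed direction without a call in 2 more and heat shock genes in 1 more.

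Around arteries, the junction list ranked higher in tau (median 0.27, 16 of 16 above 0, camera adjusted p = 0.000849, adjusted p = 0.459 with estimated correlation), with Etv5 at 0.64 ± 0.184 and Utrn at 0.35 ± 0.14 (SE, n = 6 and 6). So did neutrophil and mast cell markers (median 0.34, 7 of 7, camera adjusted p = 0.0382, adjusted p = 0.681 with estimated correlation; S100a9 0.59). Oxidative phosphorylation (-0.13), fatty acid use (-0.11), immediate early (-0.08) and circadian clock genes (-0.06) ranked lower, each with a camera adjusted p of 0.00413, as did autophagy and lysosome genes (-0.02; 0.0396). The autophagy call ended with slide as a covariate (camera adjusted p = 0.107, and 0.000303 to 0.998 over all alternatives). With estimated correlation the adjusted p was 0.459 for immediate early genes, 0.541 for circadian clock genes and 0.681 for the other lists. Taf13 had the smallest p (0.56 ± 0.127, by slide 0.54, 0.29 and 0.78). Next came the nuclear import receptor gene Ipo8 (0.51 ± 0.13), the nucleotide pyrophosphatase gene Dctpp1 (0.60 ± 0.155), Cdkn1a (0.55 ± 0.143) and Dad1 (0.53 ± 0.149). In this comparison limma called 0 genes (lowest adjusted p 0.980, 219 at an unadjusted p under 0.05), and 0 with slide as a covariate (1360). The artery's own markers Acta2 (-0.70 ± 0.496) and Myh11 (-0.01 ± 0.191) did not pass. With the negative probe value as a covariate oxidative phosphorylation ranked higher in tau. Calls were lost in 14 of 26 alternatives for neutrophil and mast cell markers, and of 27 in 13 for autophagy, 11 for oxidative phosphorylation and 10 for fatty acid use. The direction changed without a call in 3 more for autophagy, 2 for oxidative phosphorylation and 1 for fatty acid use.

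Within labelled females (4 tau, 3 control) and labelled males (2 tau, 3 control), the question was whether tau acted alike in both sexes. In labelled females the junction list ranked higher (median 0.24, camera adjusted p = 8.1e-09, adjusted p = 0.130 with estimated correlation, Ache 0.68, Etv5 0.49). Of the 10 lists called there by camera 3 ranked higher and 7 lower, and 0 kept the call with estimated correlation. Among single genes the smallest p belonged to the membrane dipeptidase gene Dpep1 (-0.46 ± 0.124), Gm4841 (-0.51 ± 0.146), the Y-linked Gm20792 (-0.76 ± 0.239), Amd1, which encodes an enzyme of polyamine synthesis (-1.18 ± 0.396), and Taf13 (0.38 ± 0.131). In labelled males fast fibre genes (median -0.62), oxidative phosphorylation (median -0.52, camera adjusted p = 1.3e-10) and glycolysis (-0.38) ranked lower. Denervation genes ranked higher (0.45), with Ankrd1 at 1.46 ± 0.351, and the lowest adjusted p of any list was 0.825 with estimated correlation. Of 25 alternatives fast fibre genes changed direction without a call in 4 and lost the call in 4 more, oxidative phosphorylation in 3 and 2, and glycolysis in 1 and 7. The smallest p values were those of the beta globin gene Hbb-b2 (1.38 ± 0.28), the calcium channel subunit gene Cacna2d1 (0.73 ± 0.152), Ipo8 (0.59), the cortisone reductase gene Hsd11b1 (0.66 ± 0.145) and Ms4a4c (0.93 ± 0.211). Limma called 0 genes in labelled females (lowest adjusted p 0.9999, 35 at an unadjusted p under 0.05). It called 0 in labelled males (lowest adjusted p 0.796, 507 at an unadjusted p under 0.05). With slide as a covariate it called 5 in labelled males, named after their values were seen: Amd1 (2.08), Cyp2d12 (1.12), Hbb-b2 (1.22), Rgs19 (0.93) and Dyrk2 (1.13). Amd1 followed the Y-linked genes over the 12 animals. Its log2 value was 7.66 to 8.82 in C2, C3, C16, T13, T14 and T15, where Eif2s3y was 5.20 to 6.54. It was 6.19 to 6.98 in C20, C30, C40, T7, T20 and T30, where Eif2s3y was 3.44 to 4.58. The contrasts by labelled sex therefore compare animals that also differ in Y-linked expression.

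The difference between the labelled sexes in the effect of tau was widest by p for Gm4841 (1.17 ± 0.228), Amd1 (3.06 ± 0.617), Hbb-b2 (1.68 ± 0.364), Dpep1 (0.91) and Hsd11b1 (0.89). Endothelial markers ranked higher (median 0.38, 16 of 19 above 0, camera adjusted p = 0.00266, adjusted p = 0.841 with estimated correlation), with the sialomucin gene Emcn at 0.69 ± 0.207. Oxidative phosphorylation ranked lower (median -0.63, lowest adjusted p of any list 0.841 with estimated correlation). For this difference limma called 0 genes (lowest adjusted p 0.999, 200 at an unadjusted p under 0.05). With slide as a covariate it called 2, Amd1 (3.36) and Igfbp5 (1.38), named after their values were seen. The Y-linked genes moved with this contrast: Eif2s3y differed by 2.99 and Ddx3y by 2.16. Between labelled males and labelled females among controls (n = 3 and 3), Dpep1 (-0.69 ± 0.132), Hsd11b1 (-0.66 ± 0.129), Gm4841 (-0.69), Amd1 (-1.83 ± 0.423) and the globin gene Hbb-b1 (-1.86 ± 0.403) had the smallest p. Endothelial markers ranked lower in labelled males (median -0.26, 1 of 19 above 0, camera adjusted p = 0.000146, adjusted p = 0.243 with estimated correlation), with Emcn at -0.57 ± 0.142. So did fibro-adipogenic progenitor markers (-0.22), extracellular matrix (-0.23) and immediate early genes (-0.34), among 8 lists that all ranked lower. The lowest adjusted p of these 8 with estimated correlation was 0.243. Between them limma called 0 genes (lowest adjusted p 0.9996, 287 at an unadjusted p under 0.05) in a fit that ignores slide, although each slide holds 1 labelled male and 1 labelled female control. Adding slide as a covariate, chosen after the data were seen, gave 2 calls, both lower in labelled males: Amd1 (-1.83 ± 0.244) and the lipoprotein receptor gene Vldlr (-0.90 ± 0.135), with 1364 at an unadjusted p under 0.05. The lowest limma adjusted p was then 0.0213, and ran from 0.00176 to 0.99998 over all alternatives.

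Region types were compared within animals to ask how the surroundings of fibres differ from normal fibres. Beside arteries, 36 of 36 oxidative phosphorylation genes were higher than in normal fibres of the same animals (median 0.24, 33 past the threshold adjusted over the list alone and 0 over all genes, camera adjusted p = 2.7e-22, adjusted p = 0.252 with estimated correlation). They include Uqcrc1 of complex III (0.36 ± 0.0909) and the ATP synthase gene Atp5g1 (0.29). Fatty acid use was higher (median 0.30, 17 of 19 above 0, 16 adjusted over the list alone, camera adjusted p = 1.6e-11, adjusted p = 0.249 with estimated correlation), with the fatty acid binding protein gene Fabp3 at 0.58 and Acadvl at 0.41. Of the connective tissue genes, fibro-adipogenic progenitor markers were higher (median 0.23, 14 of 16, 9 adjusted over the list alone, camera adjusted p = 1.3e-06, adjusted p = 0.249 with estimated correlation), with the decorin gene Dcn at 0.46 ± 0.123, Fbn1 at 0.42 and Gsn at 0.65. Extracellular matrix genes were higher (median 0.15, 18 of 22, 8 adjusted over the list alone, camera adjusted p = 0.000222, adjusted p = 0.256 with estimated correlation), with the collagen genes Col1a1 at 0.37 and Col3a1 at 0.36. Smooth muscle markers of the vessel wall were higher too (median 0.20, 9 of 10, 3 adjusted over the list alone, camera adjusted p = 0.000222, adjusted p = 0.249 with estimated correlation). Smooth muscle myosin Myh11 stood at 0.43 ± 0.131 and Tagln at 0.30, and Acta2 at 1.14 ± 0.73.

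Endothelial markers near arteries had a median of 0.08 (13 of 19 above 0, 2 adjusted over the list alone, camera adjusted p = 0.0198, adjusted p = 0.256 with estimated correlation). Among them Egfl7 stood at 0.30, Fabp4 at 0.31 and Pecam1 at -0.11 ± 0.0774. Pericyte markers had a median of 0.10 (camera adjusted p = 0.0341, adjusted p = 0.260 with estimated correlation), with Rgs5 at 0.20. Antigen presentation (0.27; H2-K1 0.44), complement (0.17; C3 0.50), oxidative stress (0.12; Cat 0.34), the unfolded protein response (0.09), glycolysis (0.11), immediate early (0.10), heat shock (0.07), microtubule (0.07) and autophagy genes (0.05) also ranked higher. Neutrophil and mast cell markers ranked lower (-0.13, camera adjusted p = 0.0196). None of the 17 lists kept its call with estimated correlation (lowest adjusted p 0.249). The ferritin light chain gene Ftl1 had the smallest p, at 6.54 ± 0.39 beside arteries and 6.09 ± 0.38 in normal fibres (SD, n = 12 pairs), a difference of 0.45 ± 0.104 (SE). Next came Crip1 (0.53 ± 0.126), Clec3b (0.53 ± 0.133), Igfbp4 (0.43 ± 0.107) and the tubulin gene Tuba1b (0.31 ± 0.0791). Limma called 0 genes (lowest adjusted p 0.311). A nominal 5% of the genes is 509.4, random splits gave a median of 227, and 1405 had an unadjusted p under 0.05. That count was 438 with 1 region per animal and type (lowest adjusted p 0.892, and 0.0790 to 0.892 over all alternatives) and 794 with the negative probe value as a covariate. The fatty acid call ended with 1 region per animal and type (camera adjusted p = 0.0780, and 2.8e-13 to 0.249 over all alternatives). Of the 17 lists each lost its call in at least 1 of 23 or 24 alternatives: heat shock in 18, microtubule in 13, autophagy in 12, endothelial and pericyte in 9 each, glycolysis, immediate early, antigen presentation and complement in 8 each, the unfolded protein response in 7 and neutrophil and mast cell markers in 5. Oxidative stress lost it in 3, fatty acid use and fibro-adipogenic progenitor markers in 2 each, and the other 3 in 1, the estimated correlation. Antigen presentation and complement each changed direction without a call in 1 more.

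In nerve bundle regions Dcn was higher than in normal fibres (7.69 ± 0.79 and 7.08 ± 0.76, SD, n = 12 pairs), by 0.61 ± 0.147 (SE), without passing. Next came the growth factor antagonist gene Spry1 (0.44 ± 0.121), Alpl (0.46 ± 0.127), the autotaxin gene Enpp2 (0.40 ± 0.112) and Crym (0.40 ± 0.112). Acta2 stood at 0.83 ± 0.284. Schwann cell markers as a list were not called (median 0.02), although the myelin gene Pmp22 (0.54 ± 0.153), 1 member, passed adjusted over the list alone. Junction genes ranked higher (median 0.16, 13 of 16, 7 adjusted over the list alone, camera adjusted p = 2.3e-05, adjusted p = 0.175 with estimated correlation). Ufsp1 stood at 0.70, Prkar1a at 0.48 and the receptor subunit gene Chrnd at 0.32. So did fibro-adipogenic progenitor markers (median 0.16, 13 of 16, 6 adjusted over the list alone, camera adjusted p = 3.1e-06), fatty acid use (median 0.42, 18 of 19, 15 adjusted over the list alone, camera adjusted p = 1.7e-15; Acadl 0.55, Hadhb 0.52) and smooth muscle markers (0.19, camera adjusted p = 0.000104), each with an adjusted p of 0.175 with estimated correlation. Oxidative phosphorylation (median 0.25, 36 of 36, 0 adjusted over the list alone, camera adjusted p = 6.7e-20, adjusted p = 0.409 with estimated correlation), slow fibre genes (0.18), extracellular matrix (0.11) and oxidative stress (0.07) completed the 8 lists. The adjusted p with estimated correlation was 0.547 for slow fibre genes, 0.547 for extracellular matrix and 0.462 for oxidative stress. Limma called 0 genes (lowest adjusted p 0.809, 407 at an unadjusted p under 0.05).

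Fibres with central nuclei had the fewest genes at an unadjusted p under 0.05 of the 3 region types set against normal fibres. The smallest p values were those of the antigen-presenting gene H2-Aa (0.35 ± 0.133, SE, n = 11 pairs), Pttg1ip (0.25), Clec3b (0.33 ± 0.129), the immunoglobulin gene Ighm (0.33 ± 0.13) and Gtf2h3 (0.25). Antigen presentation ranked higher (median 0.08, 7 of 11 above 0, camera adjusted p = 0.0499, adjusted p = 0.823 with estimated correlation), with Cd74 at 0.48 and H2-Ab1 at 0.31. So did satellite cell and regeneration genes (median 0.06, 10 of 13, camera adjusted p = 0.0499, adjusted p = 0.823 with estimated correlation), with the embryonic myosin light chain gene Myl4 at 0.35 ± 0.152, Vim at 0.20 and Pax7 at 0.16 ± 0.0969. That call was lost in 16 of 23 alternatives. The other lists ranked higher were oxidative phosphorylation (median 0.07, 34 of 36, camera adjusted p = 0.0138, adjusted p = 0.823 with estimated correlation), glycolysis and fatty acid use (camera adjusted p = 0.0499 and, with estimated correlation, adjusted p = 0.823 for each of these 2). Of 24 alternatives the call was lost in 15 for glycolysis, 11 for antigen presentation, 11 for fatty acid use and 6 for oxidative phosphorylation, and the last 2 changed direction in 3 more. The developmental myosin genes stood at 0.14 ± 0.106 (Myh3) and 0.02 ± 0.0887 (Myh8). Of the genes tested limma called 0 (lowest adjusted p 0.9996, 85 at an unadjusted p under 0.05). The typical 95% interval reached 0.16 to either side.

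**Figure D4:**
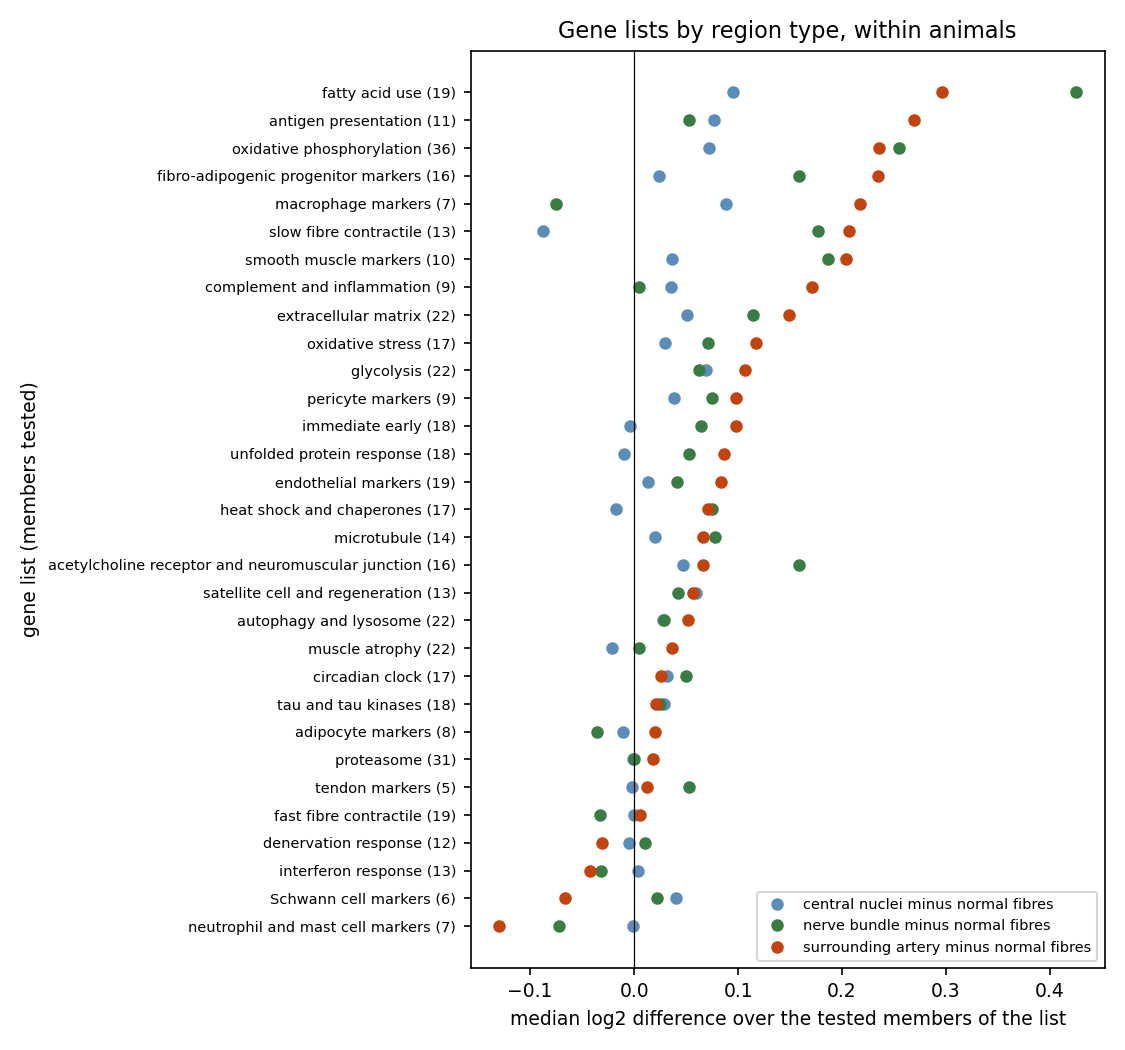
Median log2 difference of each gene list between a region type and normal fibres of the same animals, for central nuclei, nerve bundle and surrounding artery. Oxidative phosphorylation lies at 0.07, 0.25 and 0.24, and fatty acid use is highest in nerve bundle, at 0.42.

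Whether region types differed from normal fibres by another amount in tau than in control animals was tested as an interaction. A higher value means that tau minus control was higher in the region type than in normal fibres. For fast fibre genes, with slide as a covariate, median tau minus control was -0.37 in normal fibres, -0.02 in nerve bundle and -0.07 beside arteries. By these medians the positive interactions go with lower values in tau normal fibres, and the other 2 region types lie near 0. The interactions themselves were fitted without slide. The lower rank in normal fibres had a camera adjusted p of 0.591 with slide as a covariate and estimated correlation. Which region type gives rise to the interactions was not tested. For nerve bundle, the interaction of the fast fibre genes was positive (median 0.41, 17 of 19 above 0, 12 adjusted over the list alone, camera adjusted p = 3.2e-11, adjusted p = 0.191 with estimated correlation). The parvalbumin gene Pvalb stood at 0.78 ± 0.172, the fast myosin gene Myh4 at 0.89 and Actn3 at 0.83. Fatty acid use (median -0.64, 0 of 19 above 0, camera adjusted p = 4.0e-16, adjusted p = 0.191 with estimated correlation) stood lower, with the lipoprotein lipase gene Lpl at -1.34 and Cd36 at -1.07. Oxidative phosphorylation stood lower too (median -0.41, 0 of 36 above 0, camera adjusted p = 6.5e-20, adjusted p = 0.519 with estimated correlation). Among the smallest p values were those of Pvalb, Amd1 (0.91), Smox (0.80) and Ampd1 (0.88). No gene passed, with 0 called by limma (lowest adjusted p 0.795, 484 at an unadjusted p under 0.05). Beside arteries the interaction of the fast fibre genes was again positive (median 0.38, 17 of 19, 14 adjusted over the list alone, camera adjusted p = 2.0e-13, adjusted p = 0.510 with estimated correlation), with Myh4 at 0.74 and Ckm at 0.43. Glycolysis stood at 0.25, and slow fibre genes (-0.11), fatty acid use (-0.25) and macrophage markers (-0.35) lower. Each of these 4 lists had an adjusted p of 0.510 with estimated correlation. Myl2 (-0.77 ± 0.142), Ddit4l (0.67), Tmem19 (-0.75) and Mocs3 (-0.55) were among those with the smallest p. Again 0 genes were called by limma (lowest adjusted p 0.291, 578 at an unadjusted p under 0.05). For central nuclei the growth factor gene Fgf1 (-0.85 ± 0.187), Tnfaip8 (-0.49), Tmem79 (0.56), Cstf3 (0.43) and Gstk1 (-0.44) had the smallest p. Fast fibre genes stood at 0.22 and oxidative phosphorylation at -0.21 (camera adjusted p = 5.2e-07, lowest adjusted p of any list 0.771 with estimated correlation). Once more 0 genes were called by limma (lowest adjusted p 0.999, 275 at an unadjusted p under 0.05).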

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

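The tests on the sex labels and on background between slides were chosen only after the result was seen.

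All 3 measured Y-linked genes differed between the labelled sexes in the effect of tau when adjusted over the list alone (3 of 3, limma interaction), with Eif2s3y at 2.99 and Ddx3y at 2.16. Within each slide the labelled male control was below the labelled female control for Ddx3y and Eif2s3y, and the difference nearest to 0 was -0.62, which is in line with sex labels that are wrong for controls of both labels. The background between slides is argued against for Eif2s3y, since within slides its smallest difference was 5.48 SDs between regions. Ddx3y, not part of that test, differed by -1.95, -0.62 and -1.46 against SDs of 0.47, 0.16 and 0.37 on slides 1, 2 and 3. The smallest difference of Uty was -0.11 against an SD of 0.30. The 6 controls and tau animal T13 have values contrary to their label. Eif2s3y was 5.20 to 6.54 in C2, C3, C16, T13, T14 and T15 and 3.44 to 4.58 in the other animals. Read from these values, the sexes number 3 per sex and treatment, as the design text states and the labels do not. How the labels came to differ stays open, and a biological difference between the sexes was not tested. Contrasts by labelled sex therefore need the animals' genotype before they can be read.

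Among 82 groups of animals, 3 held an animal far from the others, where chance gives about 5%. For Chrna1 in tau animals over the mean of 3 region types, T13 stood at 5.18 against 5.73 for the nearest of the other animals (gap 0.685 of the range, n = 6). For H2bu2 in tau fibres with central nuclei, T7 stood at 6.16 against 6.56 (gap 0.740 of the range, n = 5). For Ube2r2 in control nerve bundle, C20 stood at 5.03 against 5.62 (gap 0.666 of the range, n = 6).

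Other lists held members whose effect of tau differed between labelled sexes or region types when adjusted over the list alone, in limma interaction tests that called 0 genes over all genes (200 at an unadjusted p under 0.05 for labelled sex, 484 for nerve bundle and 578 for surrounding artery). Between the labelled sexes 1 fibro-adipogenic progenitor marker and 1 red blood cell marker differed. Between nerve bundle and normal fibres 12 fast fibre genes differed, and 1 member each of the microtubule, pericyte, macrophage and B and plasma cell lists. Between surrounding artery and normal fibres 14 fast fibre genes and 2 oxidative stress genes differed, and 1 member each of the microtubule, slow fibre and macrophage lists.

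The negative probes, which the comparisons do not use as a measurement, were 0.23 log2 units higher in tau animals within slides (n = 12 animals, two-sided exact permutation p = 0.0463).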

How the results depend on the processing

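The array weights, the negative probe as a covariate or subtracted together with slide, slide for the labelled sexes in controls, and the omission of slide 2 or of shallow regions were chosen only after the results were seen. All reported counts are 0, so they cannot show how stable a result is: limma called 0 genes again in 372 of the counts under alternatives and more in 18, while the number at an unadjusted p under 0.05 ran from 39 to 2983 over all regions. The cause was not tested. With slide as a covariate limma called 51 genes in tau normal fibres, 1 in central nuclei, 5 in labelled males, 2 in the interaction with labelled sex and 2 between labelled sexes in controls. The negative probe as a covariate gave 1 in nerve bundle and 1 in that interaction, and slide with the negative probe gave 2 in labelled females and 3 in that interaction. Without slide 2 there were 2 in central nuclei, 1 in nerve bundle and 1 in that interaction. Array weights gave 3 over all regions, 193 in labelled females, 2 in that interaction, 481 between labelled sexes in controls and 8 in the interaction with nerve bundle. Slide with the negative probe subtracted gave 162 in central nuclei. Without each animal in turn limma called from 0 to 0 genes in all 15 comparisons, while the number at an unadjusted p under 0.05 ran, for example, from 70 to 1602 over all regions and from 1107 to 1614 beside arteries. With the pairing of regions ignored (no replicate block) 0 genes were called for central nuclei, nerve bundle and artery, with 57, 118 and 156 at an unadjusted p under 0.05.

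For the named genes 18104 values kept their sign and side of the threshold, 629 changed sign without a call and 59 passed it. For list calls 2235 kept direction and call, 844 lost the call, 83 changed direction without one and 18 reversed with one; over the 13 reversed lists camera's adjusted p ran from 6.5e-19 to 0.993. The cause of the reversals was not tested. With the negative probe as a covariate the reversed adjusted p over all regions was 0.0342 for fast fibre, 0.00568 for oxidative phosphorylation and 0.0342 for glycolysis genes; in central nuclei it was 0.000977, 4.4e-13 and 0.000338 for these, 0.0451 for fatty acid use and 0.00228 for the proteasome; it was 9.4e-05 for glycolysis in nerve bundle and 0.0011 for oxidative phosphorylation near arteries. With slide and the negative probe it was 6.5e-19 for oxidative phosphorylation in central nuclei, and 0.000115 for glycolysis and 0.00438 for heat shock in nerve bundle. Without regions of 30 counts or fewer it was 0.00476 for fast fibre, 0.00162 for oxidative phosphorylation, 0.00476 for glycolysis and 0.00821 for autophagy over all regions. For fatty acid use in labelled males the reversed adjusted p was 0.0152 without tau T14, and without each animal it ran from 3.2e-08 (T15) to 0.259 (C30). The junction list over all regions kept its call in 24 alternatives and lost it with the negative probe subtracted (adjusted p 0.0539) and with an estimated correlation (0.287), a range over alternatives of 6.8e-11 to 0.287.

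The planned count tests on recovered counts were not run, and the planned fit without animals whose Y-linked values contradict the labelled sex could not be fitted, since it leaves no controls. Lists with under 5 members left by the strict filter have no value there. Background limits what can be read: the third quartile was 3.19 times the negative probe on slide 1, 1.72 on slide 2 and 2.33 on slide 3.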

Other observations

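The background test of the genes called lower in tau normal fibres, the test of the tagged genes and, in normal fibres, the count of splits at an unadjusted p with slide as a covariate were chosen only after the result was seen, and the tests of region types were run again after a first form, with a centred covariate, was void.

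Across animals, a higher artery minus normal difference of endothelial markers went with a higher difference of oxidative phosphorylation genes. The artery minus normal difference of the oxidative phosphorylation list was above 0 in 9 of 12 animals (mean 0.24 ± 0.24, SD) and that of endothelial markers in 8 of 12. A hypothesis that capillary-rich surroundings may carry both was tested: Pearson's r was 0.659 (two-sided permutation p = 0.0224) and Spearman's rho 0.727 (permutation p = 0.00972), with r = 0.544 without the 2 animals farthest from the median. Random lists of the same size gave as high an r in 1.79% of draws. With both measures centred within slides r was 0.739 (two-sided exact permutation p = 0.0116 over 13824 permutations within slides) and rho 0.671 (exact permutation p = 0.0292), with r = 0.581 without the 2 farthest animals. This was the only such relation computed. Both measures subtract values of the same normal fibre regions, so it cannot be told whether the relation lies in artery or in normal regions. The permutations did not hold treatment fixed.

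The authors' deposited table tags some genes, without saying what was compared. Of 9 genes with a tag for male normal that names a Q threshold, 0 had an unadjusted p under 0.05 between tau and control normal fibres in limma in labelled males, and 0 in labelled females. Of 18 tested genes with a tag for male normal fibres that itself names an unadjusted p threshold, 14 did in labelled males and 3 in labelled females, so this count is not independent of the tag. Of 4 genes with such a tag for female normal, 2 did in labelled males and 3 in labelled females. The 18 include Y-linked Ddx3y (1.04 in labelled males and -1.04 in labelled females) and Eif2s3y (1.72 and -1.15), and with them Amd1 (1.17 and -1.56) and Actr3b (0.87 and -0.90). A hypothesis that the tagged genes as a set carry the contradiction in sex labels was not borne out: 32% of 25 genes had opposite signs in labelled females, against a median of 44% in random sets, and 92.7% of random sets reached as high a share.

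The genes called lower in tau normal fibres with slide as a covariate had a median of -0.56 (46 genes, median SE 0.105). With the negative probe value added the median was -0.51 (ratio 0.909, and 0.817 to 0.986 without each animal). With depth added it was -0.47 (ratio 0.827, and 0.743 to 0.929). The genes were chosen in the same fit of the same animals, and background and depth differ between treatments within slides. These medians therefore cannot separate tau from background or depth. The 367 other genes of like level had a median of -0.10 with slide as a covariate. Both covariates ended the calls (0 with each), since the SE grew to 0.125 and 0.169 while the difference shrank less. Within slides 1 of 100 splits, the real one, gave 51 genes or more, and the highest other gave 6. At an unadjusted p under 0.05 the real split gave 1535, 2 of 100 splits gave as many and the highest other gave 1665. The count of called genes is thus rare among splits. It fell to 3 without C2 and 8 without C30, and several comparisons were split, so chance is not excluded. The difference may come in whole or in part from background or depth, or from wrong sex labels, and an effect of tau on the fibres stays open as a hypothesis.

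Oxidative phosphorylation genes were higher beside arteries than in normal fibres (median 0.24). Background as the whole cause is argued against by a median of 0.19 with the negative probe difference as a covariate (ratio 0.814, and 0.559 to 0.946 without each animal), and depth by 0.23 (ratio 0.966). With all regions 1 of 100 splits, the real one, gave 1405 genes or more at an unadjusted p under 0.05. The highest other split gave 788, and the median of the others was 227. With 1 region per animal and type the count was 438, for which no splits were run. The real count is thus rare among splits, but no gene passed and several comparisons were split, so chance is not excluded. How regions were outlined was not tested, so the fibre types within each outline stay open, and a biological difference between the surroundings of arteries and other fibres remains a hypothesis.

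No splits were made for tau in labelled males or for the interaction of tau with labelled sex. For the remaining comparisons, splits of the animals were counted that gave as many genes at an unadjusted p under 0.05 in limma, first without regard to slide. Chance could not be excluded for tau against control over all regions (202 genes; 26 of 100 splits, highest other 7051), in normal fibres (166; 43 of 100, highest other 6140), central nuclei (376; 33 of 99, 5611), nerve bundle (243; 34 of 100, 6071), surrounding artery (219; 32 of 100, 6267) and labelled females (35; 20 of 35, 4940). Splits with several times the real count point to a structure of the samples, and slide explained 88.1% of the first principal component. With slide as a covariate and splits within slides, counts were higher, but chance could not be excluded over all regions (2099 genes, 7 of 100 splits, highest other 3714), in central nuclei (1907, 5 of 99, 3300), nerve bundle (1033, 12 of 100, 3682) or surrounding artery (1360, 9 of 100, 2188). For labelled females the 12 splits within slides are too few for a share under the threshold (1077 genes with slide as a covariate, 4 of 12 splits, highest other 2907). The 10 splits of the controls are too few for a share under the threshold (287 genes between labelled sexes, 4 of 10 splits, highest other 4968). Chance could not be excluded for central nuclei (85; 95 of 100, 793) or nerve bundle (407; 14 of 100, 1263) against normal fibres, nor for the interactions of tau with central nuclei (275; 85 of 100, 1804), nerve bundle (484; 31 of 100, 1588) and surrounding artery (578; 22 of 100, 1654).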
